A study of Arabidopsis thaliana with 16 samples.

How the data were processed

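The deposited tables hold, per the labels, the count of reads for each gene and library, and no other unit was used. The submitters' processing notes name HISAT2 2.0.4 for alignment, SAMtools 0.1.12 and the TAIR10 genome build. The tool that counted reads, its strand setting and its treatment of reads with several matches are not given in the sources used here, so counts of overlapping or antisense genes and of near-identical copies such as the LHCB1 and LHCB2 genes are uncertain. Each table listed 29699 genes, of which 28932 had their locus tag in the reference annotation, and 10626 of those carried a symbol. That annotation is TAIR10.1 while the count tables follow TAIR10, so genes were joined by locus tag and no coordinates are given.

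The first table holds the 12 libraries of WT, npr1-1 and npr4-4D and the second the 4 libraries of the double mutant. Libraries were assigned to groups from the sample titles. SA effects and genotype differences within the first table came from a fit of its 12 libraries (21773 genes), the SA effect in the double mutant from its own 4 libraries (21024 genes), and differences of SA effects that involve the double mutant from a fit of all 16 (22004 genes). Levels of the double mutant were not tested against other genotypes, because the table and the genotype cannot be told apart.

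Genes were filtered with filterByExpr, scaled with trimmed mean of M values (TMM) factors and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with 1 mean per group and contrasts between groups. P-values were adjusted with the Benjamini-Hochberg method over all genes of a comparison, at a threshold of 0.05. Fold thresholds were 2-fold. SE was worked back from the test, as the absolute log2 change without shrinkage divided by the square root of F. The log2 change printed beside it is edgeR's shrunken value, so SE is approximate, above all at low counts. No fold is given for groups of 3 counts or fewer.

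The 21 gene lists were fixed by symbol. Some lists share genes, and EDS1, PAD4 and SAG101 are in both the SA and NHP list and the NLR signalling list. Of 333 distinct genes, 329 were kept, and GRXC9, CRT2, ERF018 and HSP23.6 were dropped because the reference symbol at their locus differs. Lists were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, and adjusted over 294 tests of 21 lists in 14 comparisons. Of these, 151 passed 0.05 with the preset correlation and 0 passed with a correlation estimated from the data by camera. Counts of list members use the adjustment over all genes, and a second count adjusts over the list alone. Scores per library are mean log2 CPM with a prior count of 2, minus the mean of untreated WT.

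Genes were named by a fixed rule. It takes 20 marker genes, the 10 largest rises and 10 largest falls among passing genes, and the 4 members with the smallest p-value in each list. The text names a subset of these genes, and the choice of that subset was not fixed. Rises and falls needed a mean of at least 5 CPM over the libraries of the groups compared. In comparisons of 2 groups their libraries also had to show no overlap. The comparisons, lists, naming rule, tests and alternatives were set before the data were examined. The alternatives were DESeq2 1.42.0 (Wald test), DESeq2 size factors in edgeR, no low-count filter, the replicate number as a block, every library thinned to 19863178 counts, only the libraries compared, all 16 libraries in a single fit, separate fits of the 2 tables joined by a z test, and leaving out each library in turn. Fits without the npr1-1 libraries were added after the data were seen.

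The code was checked on simulated data with genes changed 1.5-, 2- and 4-fold. It recovered 32.8, 71.6 and 89.4% of them for SA in WT, 44.8, 79.1 and 97% for SA in the double mutant, 8.96, 44.8 and 77.3% for npr4-4D minus WT and 8.96, 47.8 and 78.8% for the double mutant minus WT. False calls were 6.52, 17.6, 5.47 and 6.2% in the same order. In each, 4 of 4 shifted lists and 0 of 20 null lists were called. Genes were simulated independently and lists were drawn at random, so false list calls among correlated genes were not checked. Per comparison 67, 67 and 66 genes were changed 1.5-, 2- and 4-fold, besides the shifted lists, far fewer than passed for SA in WT. Recovery and false calls depend on that number, so these shares may not carry over to the measured data.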

Results

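Messenger RNA was measured as read counts per gene in 2-week-old Arabidopsis thaliana seedlings of the Col ecotype grown on half-strength MS medium. The study asked how receptors of salicylic acid (SA), the hormone of defence against biotrophic pathogens, set the expression of defence genes. NPR1 is an SA receptor that acts as a transcriptional co-activator, and NPR3 and NPR4 are related receptors that act as co-repressors. The npr1-1 allele is a loss of NPR1 function, and npr4-4D is a dominant allele of NPR4. Wild type (WT), npr1-1, npr4-4D and the npr1-1 npr4-4D double mutant were each sampled untreated and after a spray with 50 µM SA, with 2 biological replicates in each of the 8 groups. The labels name no mock spray and no time after the spray. An SA effect below is therefore the difference between sprayed and untreated seedlings, and spraying or handling could not be told from SA itself. The 16 libraries held 19863178 to 24871490 counts each. The 4 libraries of the double mutant stand in a count table of their own, where counts at ribosomal RNA loci made up 0.521 to 0.679% of a library, against 0.045 to 0.124% in the other 12 libraries. The first principal component held 43.5% of the variance and carried both the SA treatment and the double mutant. Untreated WT lay at 3.9 and −2.8, WT with SA at −70.8 and −86.8, and the untreated double mutant at 85.4 and 79.9. With SA the double mutant lay at 55.4 and 46.5, still apart from the other genotypes. Below, log2 changes are given ± SE, levels are mean CPM (counts scaled by library size) ± SD with n = 2, and adjusted p-values come from edgeR's quasi-likelihood test.

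The genes carrying the mutations were measured first. NPR1 (AT1G64280) stood at 42.3 ± 0.78 CPM in untreated WT, 32.5 ± 0.11 in npr1-1, 37.7 ± 3.0 in npr4-4D and 31.1 ± 3.6 in the double mutant. NPR4 (AT4G19660) stood at 34.9 ± 7.4 CPM in untreated WT, 26 ± 0.99 in npr1-1, 19.4 ± 1.4 in npr4-4D and 13.6 ± 0.051 in the double mutant. NPR4 in untreated npr4-4D differed from WT by −0.84 ± 0.15 (adjusted p = 0.06). Both alleles are single-base changes, so the level of the transcript does not check the genotype labels.

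With both receptor genes intact, SA raised the regulators and enzymes of SA synthesis in WT. SARD1 (AT1G73805), a transcription factor that activates SA synthesis genes, went from 5.26 ± 0.34 to 53.3 ± 8.0 CPM, a log2 change of 3.32 ± 0.24. ICS1 (AT1G74710), the isochorismate synthase of SA synthesis, rose by 1.60 ± 0.15, EDS5 (AT4G39030), which exports the SA precursor from plastids, by 2.12 ± 0.18, and PAD4 (AT3G52430), a signalling partner of EDS1, by 1.91 ± 0.12. Of 15 genes of SA and N-hydroxypipecolic acid (NHP) synthesis and their regulators, 12 rose, 1 fell and 2 did not pass, with the same 12 and 1 adjusted over the list alone. The list rose against other genes (median 1.60, adjusted p = 2.5e-09; adjusted p = 0.29 with an estimated correlation). Among 6 genes of SA turnover 4 rose, and 4 adjusted over the list alone, including the SA hydroxylases DMR6 (AT5G24530; 3.82 ± 0.13) and DLO1 (AT4G10500; 3.90 ± 0.20) and the glycosyltransferase UGT76B1 (AT3G11340; 3.72 ± 0.27). That list had a median of 2.38 (adjusted p = 2e-09; adjusted p = 0.12 with an estimated correlation).

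Receptor and co-factor genes responded to SA in WT as well. NPR3 (AT5G45110) rose by 1.94 ± 0.14, NPR4 by 1.26 ± 0.14, NPR1 by 0.82 ± 0.089 and NIMIN2 (AT3G25882), whose product binds NPR1, by 4.74 ± 0.27. Of 16 NPR, TGA and NIMIN genes, 8 rose and 1 fell, or 8 and 2 adjusted over the list alone (adjusted p = 0.00028; adjusted p = 0.29 with an estimated correlation). Of 33 WRKY transcription factor genes, 25 rose and none fell, or 27 rose adjusted over the list alone, with WRKY38 (AT5G22570) up by 6.17 ± 0.17, WRKY51 (AT5G64810) by 4.55 ± 0.24 and WRKY70 (AT3G56400) by 2.61 ± 0.27. The WRKY list had a median of 1.80 (adjusted p = 4.7e-16; adjusted p = 0.28 with an estimated correlation). PR1 (AT2G14610), the classical SA marker, was at 0.199 ± 0.28 CPM untreated and 47.9 ± 25 CPM with SA (adjusted p = 8e-05). PR2 (AT3G57260), a glucanase, rose by 4.14 ± 0.62 and PR5 (AT1G75040) by 1.79 ± 0.25, and these 3 were the pathogenesis-related genes that rose among 5 tested, also adjusted over the list alone (adjusted p = 0.046; adjusted p = 0.47 with an estimated correlation). That list call was lost without WT untreated replicate 1 (adjusted p = 0.076).

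Immune signalling, detoxification and protein folding genes also rose with SA in WT. Of 21 genes of pattern-triggered immunity 17 rose, or 17 with 1 that fell adjusted over the list alone, among them the receptor kinase SOBIR1 (AT2G31880; 1.79 ± 0.13) and the kinase MKK4 (AT1G51660; 1.96 ± 0.15). Their median was 1.21 (adjusted p = 3.8e-12; adjusted p = 0.27 with an estimated correlation). Of 15 genes of NLR immune receptor signalling 13 rose, and 13 adjusted over the list alone, such as the helper receptor gene ADR1-L1 (AT4G33300; 1.34 ± 0.098; adjusted p = 3.4e-09 for the list; adjusted p = 0.17 with an estimated correlation). Of 24 glutathione transferase and detoxification genes 18 rose, and 18 adjusted over the list alone, with GSTF8 (AT2G47730) up by 2.16 ± 0.13 (adjusted p = 8.1e-07 for the list; adjusted p = 0.45 with an estimated correlation). Of 17 genes of folding and secretion in the endoplasmic reticulum (ER) 12 rose, and 12 adjusted over the list alone, with ERDJ3A (AT3G08970) up by 3.57 ± 0.20 and the calreticulin gene CRT3 (AT1G08450) by 1.76 ± 0.13 (adjusted p = 2.9e-07 for the list; adjusted p = 0.32 with an estimated correlation).

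Heat shock genes showed the largest list median in WT. HSP90.1 (AT5G52640), a cytosolic chaperone, went from 15.7 ± 1.6 to 1260 ± 260 CPM, a log2 change of 6.30 ± 0.43, and HSP70 (AT3G12580) rose by 5.04 ± 0.38. Of 8 heat shock genes 7 rose, and 7 adjusted over the list alone, with a median of 5.07 (adjusted p = 2.3e-12; adjusted p = 0.16 with an estimated correlation). Of 19 touch and wounding genes 8 rose and 1 fell, or 10 and 1 adjusted over the list alone, with the calmodulin-like gene TCH3 (AT2G41100) up by 1.80 ± 0.20 (adjusted p = 0.022 for the list; adjusted p = 0.58 with an estimated correlation). The touch list call was lost without WT untreated replicate 2 (adjusted p = 0.072). Small heat shock protein genes share sequence with near-identical copies, so their separate counts are uncertain.

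Photosynthesis genes fell with SA in WT. LHCB3 (AT5G54270), of the light-harvesting antenna of photosystem II, changed by −1.82 ± 0.16 and LHCA4 (AT3G47470), of the antenna of photosystem I, by −1.75 ± 0.17. Of 26 photosynthesis genes 17 fell and none rose, or 18 fell adjusted over the list alone (median −0.74, adjusted p = 1.8e-08; adjusted p = 0.48 with an estimated correlation). The neighbouring ferric reductase genes FRO6 (AT5G49730; −3.48 ± 0.21) and FRO7 (AT5G49740; −3.10 ± 0.18) and the transporter gene UMAMIT47 (AT3G28080; −3.11 ± 0.15) were among the 10 largest falls.

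The remaining 9 lists did not pass in WT. Of 9 camalexin and indole glucosinolate genes 3 rose and 1 fell, also adjusted over the list alone (list adjusted p = 0.3). Jasmonate synthesis had 5 of 10 genes up, or 5 up and 1 down adjusted over the list alone (0.11), and jasmonate response 4 up and 1 down of 19, also adjusted over the list alone (0.37). Of 21 auxin response genes 5 rose and 3 fell, also adjusted over the list alone (0.86), with a median of −0.18, a mean of 0.04 and a test leaning down. Of 12 abscisic acid response genes 1 rose and 2 fell, or 0 and 1 adjusted over the list alone (0.78). Cell wall expansion had 2 up and 3 down of 7, also adjusted over the list alone (0.16). Circadian clock had 5 down of 13, or 2 up and 5 down adjusted over the list alone (0.12). Low oxygen response had 2 down of 13, also adjusted over the list alone (0.23), and root cell markers 1 down of 17, or 0 adjusted over the list alone (0.74).

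Across the transcriptome SA raised 4588 and lowered 4272 of 21773 genes tested in WT, or 40.7% of them, with 1571 rising and 960 falling at least 2-fold. The count stayed within 1.5 times of 8860 without any 1 of the 4 WT libraries, at 6097 to 8201.

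**Figure D1:**
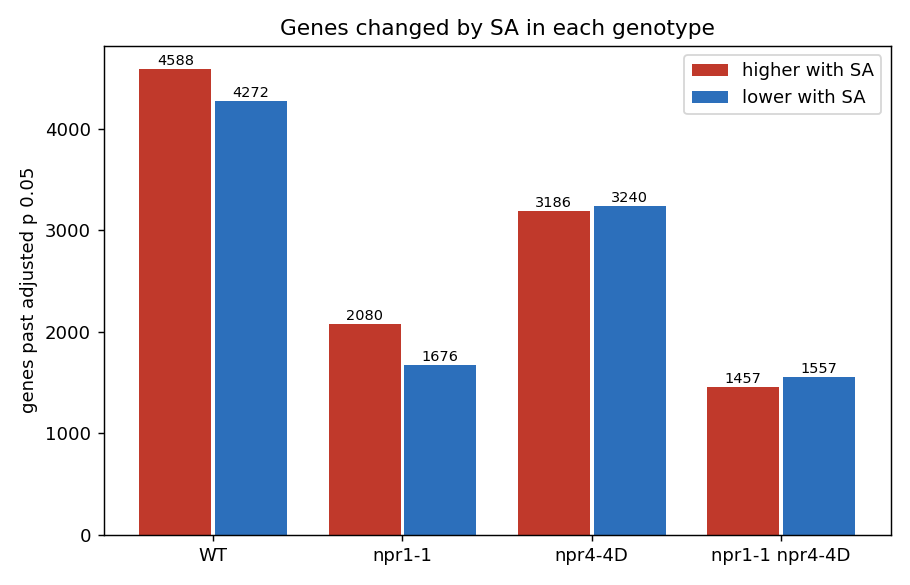
Bars give the number of genes higher or lower with SA at an adjusted p under 0.05 (vertical axis, number of genes) in each genotype (horizontal axis), with the count printed on each bar. WT had 4588 higher and 4272 lower genes and the double mutant, tested on its 4 libraries alone, 1457 and 1557.

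What remains of the response without functional NPR1 was tested in npr1-1. SARD1 still rose, from 2.37 ± 0.77 to 11.5 ± 1.8 CPM (2.24 ± 0.27), as did WRKY70 (1.54 ± 0.28), WRKY38 (2.83 ± 0.31) and NPR3 (1.06 ± 0.14). PR1 was at 0.46 ± 0.22 CPM untreated and 0.918 ± 0.44 with SA (adjusted p = 0.59), and values for ICS1 (−0.08 ± 0.16), PR2 (0.10 ± 0.74) and NIMIN2 (0.99 ± 0.34) did not pass. Of the 15 SA and NHP genes 5 rose and 1 fell, or 8 and 2 adjusted over the list alone (median 0.42, adjusted p = 0.015; adjusted p = 0.67 with an estimated correlation). Of 33 WRKY genes 12 rose, or 16 adjusted over the list alone (median 1.28, adjusted p = 3.5e-11; adjusted p = 0.32 with an estimated correlation). Immune signalling genes took part, with 12 of 21 pattern-triggered immunity genes up, or 16 adjusted over the list alone (adjusted p = 3.3e-12; adjusted p = 0.26 with an estimated correlation), including SOBIR1 (1.73 ± 0.13). Of 15 NLR signalling genes 9 rose, or 12 adjusted over the list alone, including ADR1-L1 (1.00 ± 0.099; adjusted p = 1.9e-09 for the list; adjusted p = 0.16 with an estimated correlation).

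Outside these lists, the largest rises in npr1-1 included PP2-A5 (AT1G65390; 6.44 ± 0.58), a lectin-like gene, LHT7 (AT4G35180; 4.68 ± 0.68), an amino acid transporter gene, and TCH3 (4.02 ± 0.22). Of 19 touch and wounding genes 7 rose and 1 fell, or 10 and 1 adjusted over the list alone (median 0.96, adjusted p = 3.5e-08; adjusted p = 0.22 with an estimated correlation). These genes started lower, with a median of −1.13 against WT in untreated npr1-1, and lay at a median of −0.81 from WT with SA. Of 26 photosynthesis genes 0 passed in edgeR, also adjusted over the list alone (median −0.11, adjusted p = 0.16), and of 8 heat shock genes 2 rose, also adjusted over the list alone (median 0.76, adjusted p = 0.051). In these npr1-1 libraries, untreated and treated alike, clock genes lay 0.85 to 0.98 above untreated WT on a mean log2 scale and low oxygen genes −1.80 to −2.45 from it, as measured per library. SA raised 2080 and lowered 1676 genes in npr1-1 (17.3% of those tested). With the libraries of each genotype fitted alone, 6614 genes passed in WT, 6329 in npr1-1 and 4620 in npr4-4D. The order of the single mutants by this count thus depended on the fit. Leaving out SA replicate 1, SA replicate 2, untreated replicate 1 or untreated replicate 2 gave 2080, 1225 (65.5% higher, against 55.4%), 1325 and 1928 genes, against 6329 when only the 4 npr1-1 libraries were fitted.

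In npr4-4D SA raised marker genes from several of the lists. NIMIN2 changed by 4.25 ± 0.27, WRKY38 by 6.26 ± 0.25, WRKY70 by 2.14 ± 0.27, SARD1 by 1.93 ± 0.29 and DLO1 by 3.48 ± 0.22, and PR1 went from 0.662 ± 0.68 to 26.3 ± 6.1 CPM. ICS1 (0.21 ± 0.16) and PBS3 (AT5G13320; 0.66 ± 0.29), the enzyme that acts after ICS1, did not pass. Of the 15 SA and NHP genes 8 rose and 1 fell, or 9 and 1 adjusted over the list alone (median 0.78, adjusted p = 0.00051; adjusted p = 0.53 with an estimated correlation). Of 6 SA turnover genes 4 rose, also adjusted over the list alone (median 2.14, adjusted p = 3.3e-11; adjusted p = 0.11 with an estimated correlation). NPR, TGA and NIMIN genes rose at 6 and fell at 1 of 16, also adjusted over the list alone (adjusted p = 1.2e-05; adjusted p = 0.2 with an estimated correlation). The lists of pathogenesis-related genes (3 of 5 up, also adjusted over the list alone, adjusted p = 0.14) and of camalexin and indole glucosinolate genes (2 of 9 up, also adjusted over the list alone, adjusted p = 0.2) did not pass. WRKY genes rose at 22 of 33, or 23 adjusted over the list alone (median 1.64, adjusted p = 2.2e-16; adjusted p = 0.26 with an estimated correlation). Heat shock genes rose at 7 of 8, also adjusted over the list alone (median 3.46, adjusted p = 3.3e-10; adjusted p = 0.18 with an estimated correlation), and 20 of 26 photosynthesis genes fell, also adjusted over the list alone (median −0.80, adjusted p = 3.2e-13; adjusted p = 0.36 with an estimated correlation). SA raised 3186 and lowered 3240 genes in npr4-4D (29.5% of those tested), and 4167 genes passed when untreated replicate 1 was left out.

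In the npr1-1 npr4-4D double mutant most SA marker genes did not pass. The log2 value with SA was 0.08 ± 0.11 for NPR3, −0.06 ± 0.14 for NPR1, 0.05 ± 0.15 for PAD4 and −0.33 ± 0.43 for SARD1, and SARD1 stood at 1.13 ± 0.38 CPM untreated and 0.89 ± 0.15 with SA. PR1 had 0 counts in both untreated libraries and in SA replicate 1, and 16 counts in SA replicate 2, and with WRKY38, WRKY51 and NIMIN1 it was too low to be tested. Of 14 SA and NHP genes tested 2 rose and 2 fell, or 3 and 2 adjusted over the list alone (median 0.06, mean −0.09, adjusted p = 0.9), and of 15 NLR signalling genes 2 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.93). The genes of those lists that moved went both ways, as with RPM1 (AT3G07040; 0.78 ± 0.12) and ADR1-L2 (AT5G04720; −0.60 ± 0.089), both immune receptor genes.

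Part of the WRKY and pattern-triggered immunity genes responded in the double mutant. WRKY genes rose at 6 and fell at 2 of 24, or 7 and 3 adjusted over the list alone (median 0.40, adjusted p = 0.036; adjusted p = 0.7 with an estimated correlation). Pattern-triggered immunity genes rose at 7 and fell at 2 of 21, or 9 and 2 adjusted over the list alone (median 0.16, adjusted p = 0.014; adjusted p = 0.38 with an estimated correlation). Both list calls were lost without SA replicate 2 (adjusted p = 0.4 and 0.074). HSFA2 (AT2G26150), a heat shock transcription factor gene, rose by 4.48 ± 0.30, HSP70 by 3.39 ± 0.12, PP2-A5 by 3.39 ± 0.13, TCH3 by 1.51 ± 0.14 and GSTF8 by 1.08 ± 0.096. Heat shock genes rose at 6 of 8, also adjusted over the list alone (median 3.07, adjusted p = 7.5e-36; adjusted p = 0.18 with an estimated correlation). Detoxification genes rose at 6 of 23, or 7 adjusted over the list alone (adjusted p = 7.2e-06; adjusted p = 0.34 with an estimated correlation), and ER folding genes at 9 of 16, also adjusted over the list alone (adjusted p = 5e-05; adjusted p = 0.49 with an estimated correlation). Photosynthesis genes fell at 9 of 26, or 15 adjusted over the list alone (median −0.33, adjusted p = 2e-11; adjusted p = 0.55 with an estimated correlation), with LHCA4 at −1.09 ± 0.13. BBX27 (AT1G68190), a B-box zinc finger gene, changed by −2.31 ± 0.20. In all, 1457 genes rose and 1557 fell of 21024 tested (14.3%), with 1132 and 1848 past the threshold without untreated replicate 1 and 2. In simulated data with few changed genes, this fit of 4 libraries gave a larger share of false calls than the other fits.

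The overlap of WT and double mutant, which share no library, was counted over 20876 genes tested in both. Of 4396 genes that rose in WT and 1457 in the double mutant, 1257 rose in both, where independent lists would share 307. Of 4240 and 1555 genes that fell, 1356 fell in both, where independent lists would share 316.

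**Figure D2:**
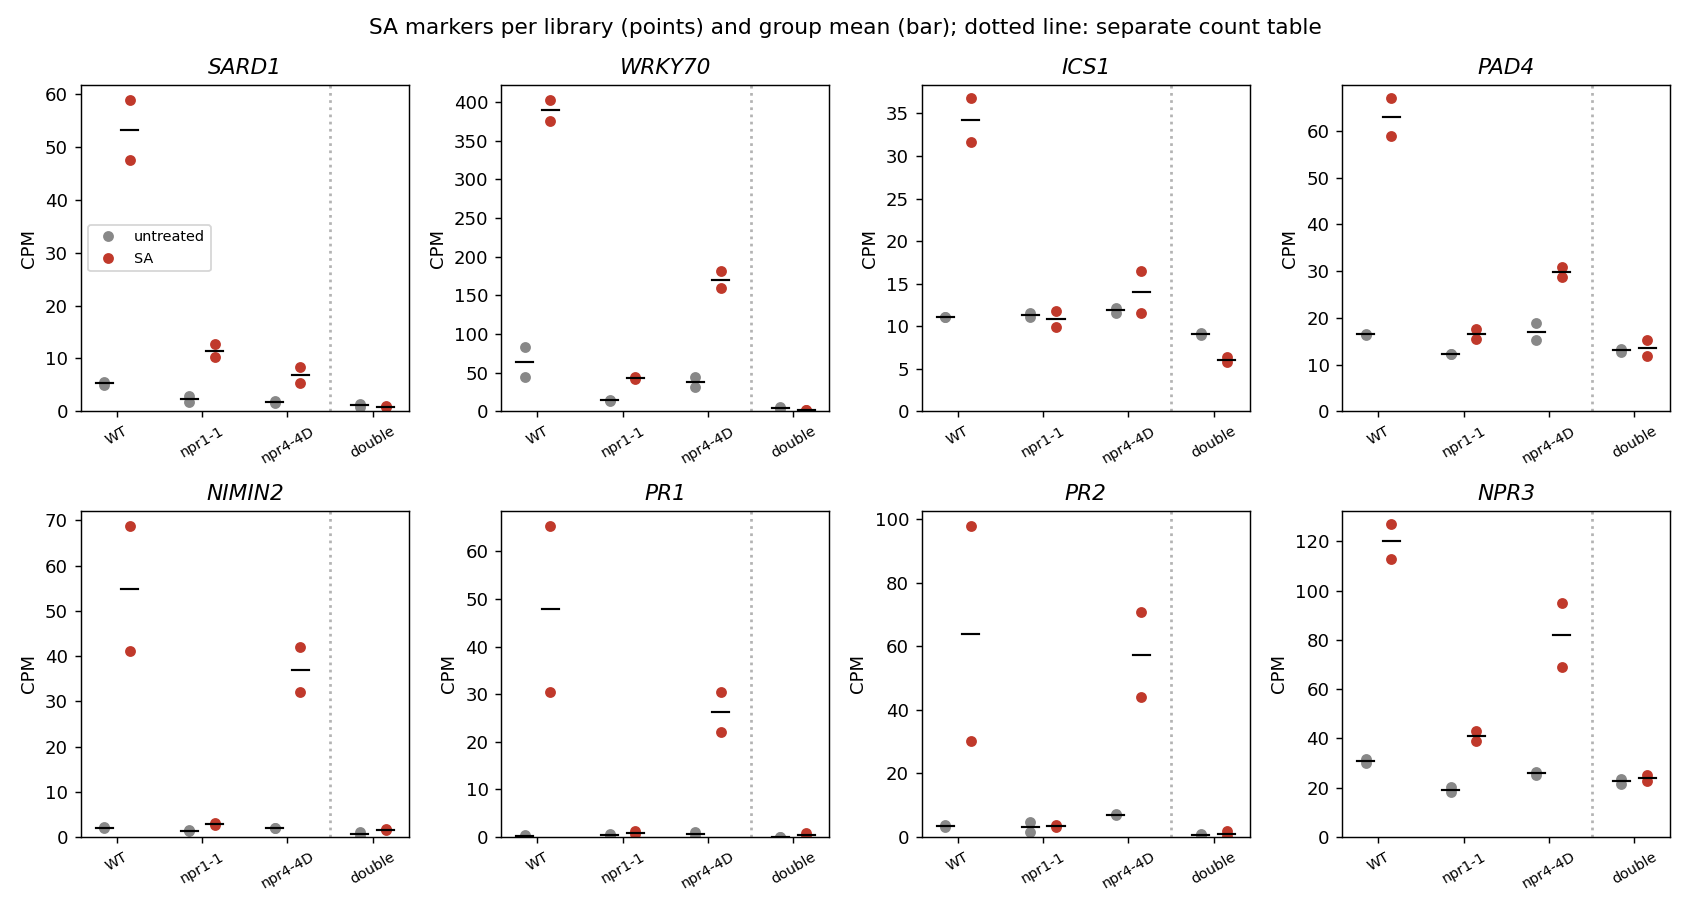
Each panel gives CPM (vertical axis, linear from 0) of a named SA marker in every library (points) with the group mean (bar), by genotype (horizontal axis), untreated in grey and with SA in red, and a dotted line sets off the double mutant of the second count table. SARD1 reached 53.3 CPM with SA in WT, 11.5 in npr1-1, 6.88 in npr4-4D and 0.89 in the double mutant.

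Whether npr1-1 weakens the SA response was tested as the difference of the SA effects. The response of ICS1 differed from WT by −1.68 ± 0.22 (adjusted p = 0.0017), of EDS5 by −1.54 ± 0.26 (0.007), of PBS3 by −3.09 ± 0.45 (0.0034), of NIMIN2 by −3.75 ± 0.45 (0.0017) and of DMR6 by −2.58 ± 0.17 (5.8e-05). SARD1 (−1.07 ± 0.36, adjusted p = 0.11) and WRKY70 (−1.07 ± 0.37, adjusted p = 0.13) did not pass. Of the 15 SA and NHP genes 6 had a lower response, or 8 adjusted over the list alone (median −1.07, adjusted p = 2e-09; adjusted p = 0.29 with an estimated correlation). Heat shock genes had a lower response at 6 of 8, also adjusted over the list alone (median −4.51, adjusted p = 7.9e-20; adjusted p = 0.11 with an estimated correlation), with HSP90.1 at −4.64 ± 0.52. Photosynthesis genes had a higher, that is less negative, response at 7 of 26, or 12 adjusted over the list alone (median 0.63, adjusted p = 8.4e-11; adjusted p = 0.43 with an estimated correlation). In the npr1-1 libraries the untreated photosynthesis score already lay 0.53 and 0.68 above untreated WT. In all 842 differences were higher and 782 lower. Of the 8 libraries, leaving out WT SA replicate 1 gave 2217 genes, WT SA replicate 2 903, WT untreated replicate 1 977 and replicate 2 923, npr1-1 SA replicate 1 735 and replicate 2 629, and npr1-1 untreated replicate 1 714 and replicate 2 704, against 1624.

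Whether npr4-4D weakens it was tested in the same way, and 0 genes passed in edgeR, with 1637 at an unadjusted p under 0.05 and 71 in DESeq2. The response of ICS1 differed from WT by −1.39 ± 0.22 and of PAD4 by −1.13 ± 0.16, each at an adjusted p of 0.094, and of SARD1 by −1.39 ± 0.39 (adjusted p = 0.46). As a group, the 15 SA and NHP genes had a lower response (0 past the threshold, 7 adjusted over the list alone, median −0.86, adjusted p = 5.3e-14; adjusted p = 0.2 with an estimated correlation). Pattern-triggered immunity genes (3 of 21 adjusted over the list alone, median −0.27, adjusted p = 8.8e-08; adjusted p = 0.36 with an estimated correlation) and heat shock genes (5 of 8 adjusted over the list alone, median −1.74, adjusted p = 9.2e-16; adjusted p = 0.12 with an estimated correlation) were lower too. Heat shock genes already lay higher in untreated npr4-4D than in WT (0 of 8 past the threshold, 3 adjusted over the list alone, median 0.81, adjusted p = 2.5e-07; adjusted p = 0.23 with an estimated correlation), and with SA they lay at a median of −1.02. SA turnover genes (1 of 6 adjusted over the list alone, median −0.25, adjusted p = 0.1) did not pass. Leaving out WT SA replicate 1 gave 7 genes, WT untreated replicate 2 gave 3 and npr4-4D SA replicate 2 gave 71. In simulated data for this difference, with few changed genes, 44.8% of genes changed 2-fold and 8.96% of genes changed 1.5-fold were recovered.

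The 2 single mutants were then set against each other. The SA response in npr4-4D minus that in npr1-1 was 1.96 ± 0.18 for DMR6 (adjusted p = 0.00046) and 2.56 ± 0.32 for DLO1 (0.003), −1.79 ± 0.22 for LHCB3 (0.0023), −1.40 ± 0.18 for the clock gene PRR7 (AT5G02810; 0.0033) and −2.75 ± 0.28 for TCH3 (0.0014). Of 6 SA turnover genes 3 responded more in npr4-4D, or 4 adjusted over the list alone (median 1.44, adjusted p = 8.5e-09; adjusted p = 0.13 with an estimated correlation). Photosynthesis genes responded in the more negative direction at 6 of 26, or 16 adjusted over the list alone (median −0.71, adjusted p = 1.4e-15; adjusted p = 0.33 with an estimated correlation). The npr1-1 libraries, whose clock genes stood apart from the other genotypes and whose touch genes started lower, enter this difference. In total 211 genes were higher and 401 lower, and leaving out npr1-1 SA replicate 1 or 2, npr1-1 untreated replicate 1 or 2, or npr4-4D untreated replicate 2 gave 221, 104, 120, 267 and 199 genes. The share of higher genes was 34.5%, and 19.9, 20.2 and 17.1% without npr1-1 SA replicate 1, npr1-1 SA replicate 2 and npr4-4D untreated replicate 2.

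In the double mutant genes of SA receptors, SA synthesis and immune signalling responded less to SA than in WT. The SA response differed from WT by −3.66 ± 0.50 for SARD1 (adjusted p = 0.0018), −4 ± 0.55 for WRKY70 (0.0034), −2.20 ± 0.22 for ICS1 (0.00031), −1.88 ± 0.19 for NPR3 (0.00031) and −0.89 ± 0.16 for NPR1 (0.0066). Of the 15 SA and NHP genes 7 had a lower response, or 9 adjusted over the list alone (median −1.75, adjusted p = 2.2e-20; adjusted p = 0.12 with an estimated correlation). NLR signalling genes had a lower response at 8 of 15, or 14 adjusted over the list alone (median −0.85, adjusted p = 1e-20; adjusted p = 0.058 with an estimated correlation), with ADR1-L1 at −1.39 ± 0.13 (adjusted p = 0.00022) and ADR1-L2 at −1.34 ± 0.12 (2e-04). Pattern-triggered immunity genes followed at 10 of 21, or 14 adjusted over the list alone (median −0.75, adjusted p = 7.7e-17; adjusted p = 0.16 with an estimated correlation). This difference spans both count tables, and each SA effect is taken within its own table. That removes a constant difference between the tables for each gene. Spraying or sampling that differed between the 2 sets of libraries could not be told from genotype. The same holds for the differences from npr1-1 and npr4-4D below. It gave 172 higher and 747 lower genes (18.7% higher), and 811 and 1399 (36.7% higher) when each table was fitted on its own. Leaving out WT SA replicate 1 or 2 gave 1686 (31.3% higher) and 368 genes, WT untreated replicate 1 gave 355, and double mutant SA replicate 1, untreated replicate 1 and untreated replicate 2 gave 377, 587 and 375. The fit without the npr1-1 libraries gave 425.

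Some immune receptor genes responded less to SA in the double mutant than in npr1-1. The double mutant minus npr1-1 difference was −1.06 ± 0.13 for ADR1-L1 (adjusted p = 0.00095), −1.07 ± 0.12 for ADR1-L2 (0.00059) and −1.09 ± 0.18 for SOBIR1 (0.0062). Untreated, these genes were lower in npr1-1 than in WT, by −0.66 ± 0.098, −0.75 ± 0.093 and −1.46 ± 0.13, and the double mutant comes from another count table. The difference was −2.59 ± 0.51 for SARD1 (0.017) and −2.93 ± 0.56 for WRKY70 (0.021). The SARD1 call was lost without npr1-1 SA replicate 2 (adjusted p = 0.061), npr1-1 untreated replicate 1 (0.061) or double mutant SA replicate 1 (0.064), SA replicate 2 (0.054) or untreated replicate 2 (0.13). The WRKY70 call was lost without npr1-1 SA replicate 2 (0.074), npr1-1 untreated replicate 1 (0.074) or 2 (0.065), or double mutant SA replicate 1 (0.069), SA replicate 2 (0.086) or untreated replicate 1 (0.087). Of 15 NLR signalling genes 4 had a lower response, or 9 adjusted over the list alone (median −0.51, adjusted p = 1e-10; adjusted p = 0.11 with an estimated correlation), and of 15 SA and NHP genes 1, or 1 higher and 1 lower adjusted over the list alone (median −0.39, adjusted p = 0.012; adjusted p = 0.61 with an estimated correlation). Pattern-triggered immunity genes were lower at 3 of 21, or 6 adjusted over the list alone (median −0.44, adjusted p = 8.8e-06; adjusted p = 0.36 with an estimated correlation). Heat shock genes went the other way at 2 of 8, or 5 adjusted over the list alone (median 2.16, adjusted p = 3e-08; adjusted p = 0.18 with an estimated correlation). Touch genes were lower at 5 and higher at 1 of 20, or 9 and 1 adjusted over the list alone (adjusted p = 2.7e-07; adjusted p = 0.2 with an estimated correlation), TCH3 by −2.53 ± 0.29. PRR7 (−1.36 ± 0.17) and LBD41 (AT3G02550; −1.12 ± 0.18) were lower among clock and low oxygen genes. For touch, clock and low oxygen genes alike the npr1-1 libraries stood apart untreated. In all 186 genes were higher and 561 lower (24.9% higher), or 680 and 1127 (37.6% higher) when each table was fitted on its own. Leaving out npr1-1 SA replicate 1 or 2 gave 391 and 195 genes, npr1-1 untreated replicate 1 or 2 gave 182 and 386, and double mutant SA replicate 2 and untreated replicate 2 gave 343 and 307.

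Against npr4-4D, the double mutant had a lower response of NPR3 (−1.58 ± 0.19), NPR4 (−1.66 ± 0.21) and DMR6 (−2.33 ± 0.23), with adjusted p of 0.0094, 0.0094 and 0.0024. Each of these 3 calls was lost without double mutant untreated replicate 1 (adjusted p = 0.059). Of 6 SA turnover genes 3 had a lower response, or 4 adjusted over the list alone (median −2.09, adjusted p = 1.2e-16; adjusted p = 0.058 with an estimated correlation), and of 15 NLR signalling genes 2, or 11 adjusted over the list alone (median −0.60, adjusted p = 7.7e-17; adjusted p = 0.062 with an estimated correlation). In all 48 genes were lower and 2 higher (4% higher), or 370 and 127 (25.6% higher) when each table was fitted on its own. The fit without the npr1-1 libraries, added after the data were seen, gave 15. Leaving out npr4-4D SA replicate 1 or 2 gave 22 and 123 (14.6% higher) genes, npr4-4D untreated replicate 1 or 2 gave 6 and 24, and double mutant SA replicate 1, untreated replicate 1 and untreated replicate 2 gave 16, 0 and 25. With 0 genes there, edgeR had 2103 at an unadjusted p under 0.05 and DESeq2 251 adjusted, both with all libraries.

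Over the SA-induced genes as a set the order of the genotypes was the same from either starting set. The 1387 genes induced at least 2-fold in WT and tested in every fit had a median log2 change of 1.54 in WT, 1.14 in npr4-4D, 0.74 in npr1-1 and 0.68 in the double mutant, with 84.4, 51.8 and 43.3% of them past the threshold in the mutants in that order. This set leaves out genes too low in the double mutant to be tested, such as PR1. Over all 1571 genes the median difference of SA effects was −0.16 for the double mutant minus npr1-1. Selecting these genes on the WT libraries raises the WT median. The 875 genes selected in npr4-4D instead had medians of 1.83 in WT, 1.56 in npr4-4D, 0.99 in npr1-1 and 0.89 in the double mutant. The 931 genes lowered at least 2-fold in WT had medians of −1.34, −1.07, −0.53 and −0.81 in WT, npr4-4D, npr1-1 and the double mutant.

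**Figure D3:**
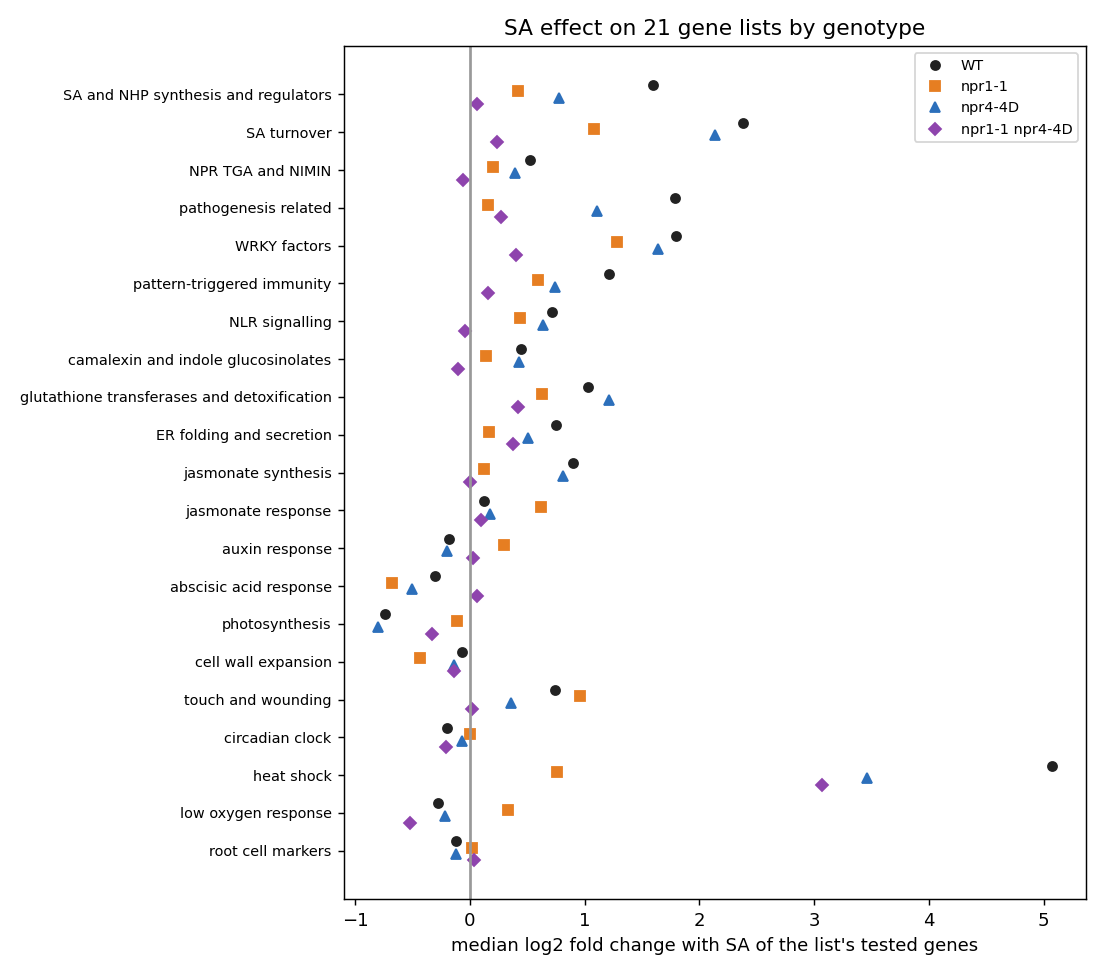
Points give the median log2 fold change with SA (horizontal axis) over the tested genes of each of 21 gene lists (vertical axis), 1 marker per genotype. Heat shock genes had medians of 5.07 in WT, 3.46 in npr4-4D, 3.07 in the double mutant and 0.76 in npr1-1, and SA and NHP genes 1.60, 0.78, 0.06 and 0.42.

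Untreated npr1-1 seedlings differed from WT in defence genes and in groups outside defence. LURP1 (AT2G14560), a defence gene that responds to oomycete infection, was lower by a log2 value of −4.15 ± 0.16, PCC1 (AT3G22231) by −3.78 ± 0.32, SOBIR1 by −1.46 ± 0.13 and NDR1 (AT3G20600) by −1.40 ± 0.14. Of 21 pattern-triggered immunity genes 10 were lower, or 11 adjusted over the list alone (median −0.41, adjusted p = 2.5e-07; adjusted p = 0.36 with an estimated correlation), and of 15 NLR signalling genes 7, or 9 adjusted over the list alone (adjusted p = 1.9e-06; adjusted p = 0.2 with an estimated correlation). Low oxygen genes were lower at 12 of 13, also adjusted over the list alone (median −2.50, adjusted p = 2.5e-52; adjusted p = 0.1 with an estimated correlation), with LBD41 at 6.62 ± 0.42 CPM against 58.1 ± 6.1 in WT. Touch genes were lower at 8 and higher at 2 of 19, or 9 and 3 adjusted over the list alone (median −1.13, adjusted p = 1.4e-08; adjusted p = 0.2 with an estimated correlation). Clock genes were higher at 7 and lower at 1 of 13, or 8 and 1 adjusted over the list alone (median 0.99, adjusted p = 2.2e-10; adjusted p = 0.17 with an estimated correlation), with PRR7 at 1.26 ± 0.12. Photosynthesis genes were higher at 13 and lower at 1 of 26, or 15 and 3 adjusted over the list alone (median 0.54, adjusted p = 1.8e-10; adjusted p = 0.45 with an estimated correlation), with LHCB3 at 1.83 ± 0.16. In the untreated double mutant, which also carries npr1-1, the low oxygen and clock scores lay at 0.00 and 0.18, and at −0.07 and 0.13, from untreated WT of the other table, while its photosynthesis scores were 0.46 and 0.53. In all 1067 genes were higher and 1740 lower (38% higher), and 946 passed without WT untreated replicate 2 (24.8% higher), 719 without npr1-1 untreated replicate 1 and 1211 without npr1-1 untreated replicate 2.

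**Figure D4:**
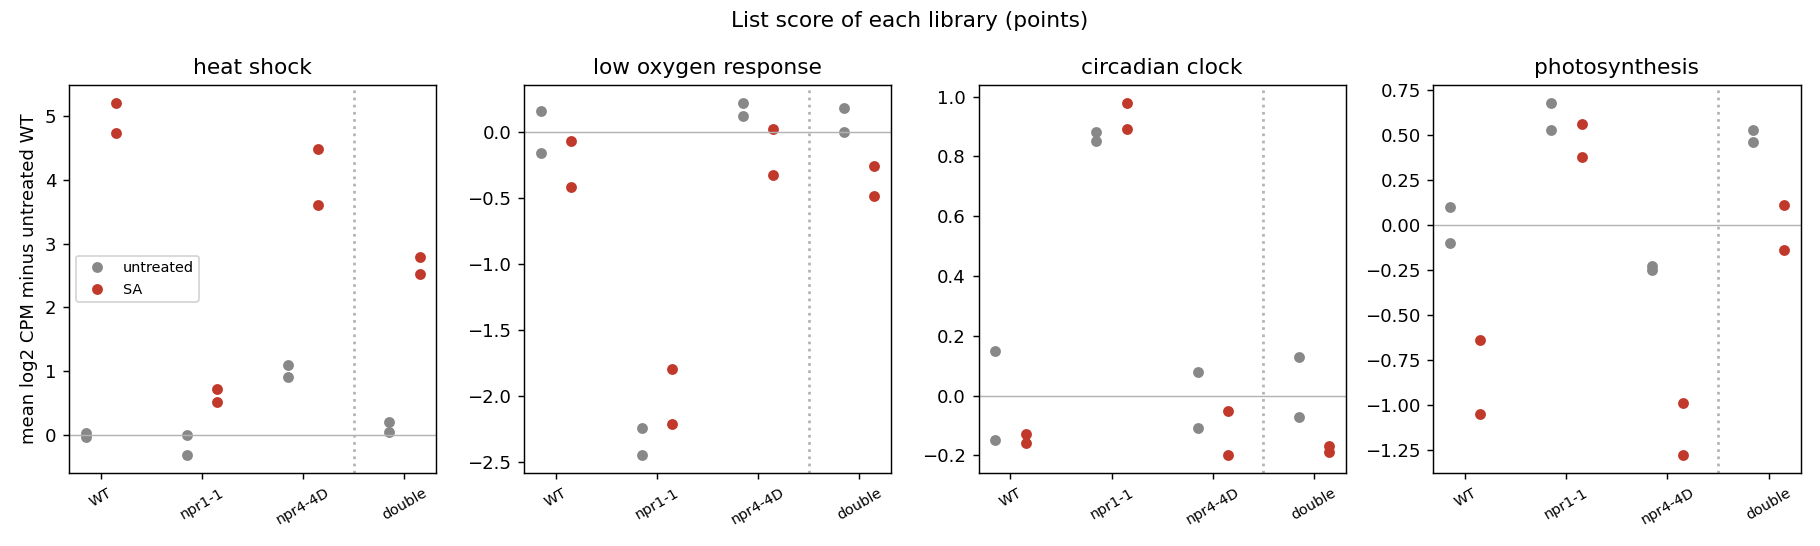
Points give, for each library, the mean log2 CPM of a gene list minus its mean in untreated WT (vertical axis) by genotype (horizontal axis), untreated in grey and with SA in red, with a dotted line before the double mutant of the second count table. The low oxygen score was −2.45 to −1.80 in the 4 npr1-1 libraries, and the heat shock score with SA was 4.74 and 5.21 in WT, 3.6 and 4.48 in npr4-4D, 2.53 and 2.79 in the double mutant and 0.51 and 0.72 in npr1-1.

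With SA, genes of SA synthesis and WRKY genes lay lower in npr1-1 than in WT. NIMIN2 was lower by a log2 value of −4.24 ± 0.25, WRKY38 by −5.42 ± 0.16, SARD1 by −2.22 ± 0.22, ICS1 by −1.66 ± 0.15, PAD4 by −1.92 ± 0.12 and PR2 by −4.22 ± 0.62, and PR1 stood at 0.918 ± 0.44 CPM against 47.9 ± 25. SA and NHP genes were lower at 10 of 15, or 11 adjusted over the list alone (adjusted p = 2.8e-13; adjusted p = 0.23 with an estimated correlation). WRKY genes were lower at 21 of 33, or 24 adjusted over the list alone (adjusted p = 4.3e-17; adjusted p = 0.26 with an estimated correlation), and heat shock genes at 7 of 8, also adjusted over the list alone (adjusted p = 1.8e-17; adjusted p = 0.12 with an estimated correlation). Photosynthesis genes were higher at 18 of 26, also adjusted over the list alone (median 1.12, adjusted p = 5.3e-26; adjusted p = 0.23 with an estimated correlation). Clock genes were higher at 8 of 13, also adjusted over the list alone (adjusted p = 6.4e-14; adjusted p = 0.14 with an estimated correlation), and low oxygen genes were lower at 12 of 13, also adjusted over the list alone (adjusted p = 1.2e-16; adjusted p = 0.2 with an estimated correlation). In all 2316 genes were higher and 3371 lower, and 3119 passed without WT SA replicate 2, 2590 without npr1-1 SA replicate 1 and 3125 without npr1-1 SA replicate 2.

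Untreated npr4-4D differed from WT at few genes, several of them neighbours. MRD1 (AT1G53480), a transcript of unknown function, stood at 0.151 ± 0.086 CPM against 14.1 ± 2.8 in WT (−6.47 ± 0.43), and the adjacent HEI10 (AT1G53490), a gene of meiotic crossover formation, differed by −2.86 ± 0.18. MAF5 (AT5G65080), a flowering regulator of the MADS-box family, differed by −3.30 ± 0.17 and TLL1 (AT1G45201), a lipase-like gene, by −2.47 ± 0.16, while AGL20 (AT2G45660), a promoter of flowering also called SOC1, was higher by 0.85 ± 0.09. MAF5 lies beside near-identical copies, so its counts are uncertain. LURP1 was lower by −1.41 ± 0.14 and the SA marker WRKY38 by −2.71 ± 0.38. Of the 15 SA and NHP genes 0 passed in edgeR, or 1 was lower adjusted over the list alone (list adjusted p = 0.92), and of 16 NPR, TGA and NIMIN genes 0, or 1 lower adjusted over the list alone (median −0.14, adjusted p = 0.00067; adjusted p = 0.29 with an estimated correlation). Of 6 SA turnover genes 1 was lower, or 2 adjusted over the list alone (median −0.11, adjusted p = 0.008; adjusted p = 0.36 with an estimated correlation). This list was lost without npr4-4D untreated replicate 2 (adjusted p = 0.33). Of 5 pathogenesis related genes 0 passed, also adjusted over the list alone (median 0.46, adjusted p = 0.0069; adjusted p = 0.36 with an estimated correlation). That list was lost without WT untreated replicate 1 (adjusted p = 0.16) or npr4-4D untreated replicate 2 (0.064). In all 10 genes were higher and 33 lower (23.3% higher), or 66 and 88 (42.9% higher) in DESeq2. Leaving out WT untreated replicate 1, npr4-4D untreated replicate 1 or npr4-4D untreated replicate 2 gave 20, 15 and 17 (35.3% higher) genes, and the fit without the npr1-1 libraries 17.

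With SA, npr4-4D was lower than WT in regulators of SA synthesis and in WRKY genes. WRKY38 differed by −2.62 ± 0.13 (adjusted p = 4.4e-06), WRKY54 (AT2G40750) by −1.90 ± 0.19 (0.00089), SARD1 by −2.95 ± 0.23 (0.00017), ICS1 by −1.29 ± 0.15 (0.0014), PAD4 by −1.08 ± 0.11 (0.00067) and DMR6 by −1.46 ± 0.12 (0.00012), while PR1 (−0.87 ± 0.44, adjusted p = 0.4) and PR2 (−0.16 ± 0.49, adjusted p = 0.92) did not pass. SARD1 stood at 6.88 ± 2.3 CPM against 53.3 ± 8.0 in WT. Part of these differences was present without SA. In untreated npr4-4D, WRKY38 lay at −2.71 ± 0.38 from WT (edgeR adjusted p = 0.016) and DMR6 at −0.84 ± 0.13 (0.028). SARD1 (−1.57 ± 0.30) and WRKY54 (−1.14 ± 0.22) were lower without passing, while ICS1 (0.10 ± 0.16) and PAD4 (0.04 ± 0.12) were not lower. The SA effect on WRKY38 differed from WT by 0.09 ± 0.47. SA and NHP genes were lower at 7 of 15, or 8 adjusted over the list alone (median −0.90, adjusted p = 9.8e-15; adjusted p = 0.2 with an estimated correlation). NLR signalling genes were lower at 5 of 15, or 9 adjusted over the list alone (adjusted p = 1.9e-09; adjusted p = 0.16 with an estimated correlation), and WRKY genes at 5 of 33, or 9 adjusted over the list alone (adjusted p = 7.1e-10; adjusted p = 0.36 with an estimated correlation). In all 67 genes were higher and 383 lower. Fitted on the 4 libraries compared alone, 14 genes passed, and SARD1 (adjusted p = 0.069), ICS1 (0.17), PAD4 (0.072) and DMR6 (0.072) did not, while WRKY38 and WRKY54 did. The fit without the npr1-1 libraries gave 142 genes, and leaving out WT SA replicate 2 or npr4-4D SA replicate 1 gave 208 and 192. Leaving out npr4-4D SA replicate 2 gave 501 genes, 258 of them among the 450, with 36.9% higher against 14.9%.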

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

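All tests of explanations in this section were chosen after the results were seen.

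In npr1-1, low oxygen genes were lower and clock and photosynthesis genes higher than in WT, untreated and with SA. A change that npr1-1 brings about could not be told from other causes, since the mean low oxygen score was 0.09 in the untreated double mutant, which lies in another table, and −2.35 in untreated npr1-1. Another time of day at harvest stays open, because the gap of 1.14 between the medians of 5 day genes (1.26) and 3 evening genes (0.12) used 8 of 13 clock genes, grouped after the clock genes were seen to differ. A smaller share of root cells did not account for the size of the fall of the low oxygen genes. The lower quartile of the root cell markers was −0.43 (median −0.23) and the upper quartile of the low oxygen genes −1.86. Root cell markers were lower at 5 and higher at 0 of 17 (camera adjusted p = 0.055; adjusted p = 0.46 with an estimated correlation). A small part of the fall could thus still come from root share. The low oxygen list also had a median difference of SA effects of −0.78 in the double mutant minus npr1-1.

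Heat shock genes responded to SA less in npr1-1, where their list did not pass, than in the other genotypes. The double mutant also carries npr1-1, and heat shock genes rose there within its own table. Their median was 3.07 (lower quartile 1.08), with 6 of 8 genes past the test. A rise in sprayed seedlings thus did not need NPR1 there. Whether a rise caused by SA itself needs NPR1 was not decided, because handling may have raised these genes. A link to the strength of the SA marker response was not decided. Double mutant minus npr1-1 differences went opposite ways, with medians of 2.16 for heat shock genes (lower quartile 0.95) and −0.39 for SA and NHP genes (upper quartile −0.24). They span both tables, and 2 of 8 heat shock genes passed. Within the first table both lists had the same order in WT, npr4-4D and npr1-1. Medians were 5.07, 3.46 and 0.76 for heat shock genes and 1.60, 0.78 and 0.42 for SA and NHP genes. Temperature or handling that differed between seedlings stays open, for the double mutant too, as the design has no mock spray, replicates of npr4-4D with SA differed by 0.88 in the heat shock score, and untreated npr4-4D scored 0.91 and 1.09 above untreated WT.

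Untreated npr4-4D differed from WT at 43 genes. Variants of the line at a few loci stay open, because the 4 neighbouring pairs among them were noticed before they were tested, and neighbours or near-identical copies may vary together or share reads. The pairs were MRD1 (−6.47) with HEI10 (−2.86), MAF4 (−1.76) with MAF5 (−3.30), AT1G26640 (−1.39) with AT1G26650 (−1.35), and AT2G07213 (3.73) with AT2G07215 (4.01). Lower basal expression of SA-induced genes stays open too, where 13 of the 33 lower genes (39.4%) were SA-induced in npr1-1, against 9.51% of other genes, and 16 in WT, which shares libraries with this comparison. Lists of SA-induced genes went both ways, with medians of 0.46 for pathogenesis related and 0.81 for heat shock genes, −0.11 for SA turnover and −0.14 for NPR, TGA and NIMIN genes. All 4 passed the list test with the preset correlation, but not with an estimated one (camera adjusted p = 0.36, 0.23, 0.36 and 0.29). Medians were 0 for WRKY and 0.10 for SA and NHP genes, which did not pass with either.

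SA effects differed between npr1-1 and WT at 1624 genes, with values of −0.88 for NPR3, −3.57 for NIMIN1, −3.75 for NIMIN2, −6.84 for PR1, −4.04 for PR2, −1.68 for ICS1, −1.54 for EDS5, −3.09 for PBS3, −2.67 for WRKY51, −3.34 for WRKY38, −1.49 for PAD4 and −0.98 for EDS1. Leaving out 1 of 8 libraries lost the call of NPR3 in 6 cases (edgeR adjusted p of 0.052 to 0.091), NIMIN1 in 5 (0.054 to 0.22), PR1 in 7 (0.051 to 0.31), PR2 in 7 (0.057 to 0.28) and EDS1 in 7 (0.054 to 0.14). The PR1 value was set by a single library, since untreated WT held 0 and 0.399 CPM. Without WT untreated replicate 2 that group was at 0 CPM and gave no usable fold. Over the libraries left out PR2 ranged from −4.65 to −2.96 and EDS1 from −1.25 to −0.64.

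Between npr4-4D and npr1-1 SA effects differed at 612 genes, with 3.26 for NIMIN2 and 3.43 for WRKY38. The NIMIN2 call was lost in 1 case (edgeR adjusted p = 0.059) and the WRKY38 call in 2 (0.059 to 0.092).

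Between the double mutant and WT they differed at 919 genes, with −0.89 for NPR1, −1.88 for NPR3, −1.61 for NPR4, −3.50 for NIMIN2, −2.20 for ICS1, −1.75 for EDS5, −2.81 for PBS3, −3.66 for SARD1, −4 for WRKY70, −4.57 for WRKY51, −1.88 for PAD4 and −1.25 for EDS1. In the double mutant WRKY51 stood at 0.227 and 0.108 CPM untreated and 0.295 and 0.0497 with SA, too low for a test there. Its difference thus rests mainly on the rise in WT. The NIMIN2 call was lost in 1 case (edgeR adjusted p = 0.23) and the WRKY51 call in 2 (0.061 to 0.25).

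Between the double mutant and npr1-1 they differed at 747 genes, with −0.76 for NPR1, −1.01 for NPR3, −0.95 for NPR4, −2.59 for SARD1 and −2.93 for WRKY70. Calls were lost in 5 cases for NPR1 (edgeR adjusted p of 0.068 to 0.1), 3 for NPR3 (0.058 to 0.073), 7 for NPR4 (0.061 to 0.11), 5 for SARD1 (0.054 to 0.13) and 6 for WRKY70 (0.065 to 0.087). Between the double mutant and npr4-4D they differed at 50 genes, with −1.58 for NPR3, −1.66 for NPR4 and −3.54 for WRKY70. Calls were lost in 1 case each for NPR3 and NPR4 (0.059) and in 6 for WRKY70 (0.088 to 0.18).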

How the results depend on the processing

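Each group had 2 libraries, SA was given without a mock spray and the double mutant was in its own table. Counts of genes depended on the fit. DESeq2 gave 71 genes for the difference of SA effects npr4-4D minus WT (edgeR 0), 1044 for npr4-4D minus npr1-1 (612), 251 for the double mutant minus npr4-4D (50) and 154 for untreated npr4-4D minus WT (43). With only the libraries compared, SA gave 6614 genes in WT (8860), 6329 in npr1-1 (3756) and 4620 in npr4-4D (6426). That setting gave 14 for npr4-4D minus WT with SA (450). Separate fits of the tables gave 2210, 1807 and 497 for the double mutant minus WT, npr1-1 and npr4-4D (919, 747 and 50). Fits without the npr1-1 libraries, added after the data were seen, gave 17 for untreated npr4-4D minus WT, 142 for npr4-4D minus WT with SA, 425 for the double mutant minus WT and 15 for the double mutant minus npr4-4D. The cause was not tested. Replicates of npr1-1 lay closer together than those of WT and npr4-4D. The chi-square per degree of freedom between replicates was 6.73 untreated and 5.05 with SA in npr1-1, against 13.6 to 23.3 in WT and npr4-4D. DESeq2 size factors in edgeR, no low-count filter and thinning to 19863178 counts moved none of the 14 counts by more than 1.5 times.

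Leaving out 1 library gave 1225 to 2080 genes for SA in npr1-1, 4167 to 5141 in npr4-4D and 1132 to 2415 in the double mutant. For differences of SA effects it gave 629 to 2217 for npr1-1 minus WT, 0 to 71 for npr4-4D minus WT, 104 to 569 for npr4-4D minus npr1-1, and 355 to 1686, 182 to 532 and 0 to 123 for the double mutant minus WT, npr1-1 and npr4-4D. For levels it gave 719 to 1880 and 15 to 29 for untreated npr1-1 and npr4-4D minus WT, and 2590 to 5464 and 192 to 528 with SA. The library left in its group was assumed to vary like the other groups. Of the calls of named genes 770 were lost and 2674 kept in these fits, with none reversed, and of list calls 60 were lost and 803 kept. The WRKY list in npr4-4D minus WT reversed its sign without WT SA replicate 2 (adjusted p = 0.77), and had an adjusted p of 2.2e-08 without WT SA replicate 1. Under the other settings 173 calls of named genes were lost and 4269 kept, and all 151 list calls were lost with an estimated correlation.

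Treated and untreated libraries share only a replicate number. Correlations of replicate differences between untreated and SA groups were 0.14 in WT, 0.09 in npr1-1, 0.06 in npr4-4D and 0.01 in the double mutant over 16273 genes, within the −0.50 to 0.45 seen over all 28 pairs of groups, so no pairing was used. With the replicate number as a block the counts were 8580, 3659, 6187 and 3009 for SA in WT, npr1-1, npr4-4D and the double mutant. They were 1430, 0 and 533 for npr1-1 minus WT, npr4-4D minus WT and npr4-4D minus npr1-1, and 964, 716 and 65 for the double mutant minus WT, npr1-1 and npr4-4D. For levels the block gave 2618 and 33 for untreated npr1-1 and npr4-4D minus WT, and 5428 and 397 with SA.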

Other observations

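The jasmonate response list leaned higher in untreated npr4-4D than in WT. Of 19 genes 0 passed in edgeR, or 2 were higher adjusted over the list alone (median 0.53, adjusted p = 3.1e-05; adjusted p = 0.46 with an estimated correlation), and the list call was lost without npr4-4D untreated replicate 2 (adjusted p = 0.12).

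Low oxygen genes fell with SA in the double mutant at 6 of 13, or 9 adjusted over the list alone (median −0.52, adjusted p = 3.3e-05; adjusted p = 0.51 with an estimated correlation). LBD41, a transcription factor gene induced by low oxygen, changed by −0.73 ± 0.092.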
